A study of Procotyla fluviatilis with 12 samples.

How the data were processed

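The series holds 12 RNA-seq libraries of *Procotyla fluviatilis*, a freshwater planarian in which, per the labels, one body region is proficient in regeneration (Reg+, amputated anterior to the pharynx) and another is deficient (Reg-, amputated posterior to the pharynx). Per the labels' protocols, worms were collected in the field and kept briefly in the laboratory, tissue near the wound was excised 24 hours after amputation, matching tissue was taken from uncut worms, and RNA came from pools of 3 worms. TruSeq RNA libraries were sequenced on an Illumina HiSeq, per the labels' protocols. The titles place 3 libraries in each of 4 groups: Reg+ amputated, Reg+ uncut, Reg- amputated and Reg- uncut. Replicate numbers are those of the titles (1, 2 and 3, and for Reg- uncut 1, 3 and 4). The labels do not say whether pools of one group came from separate collections or days, so p-values measure the spread between these pools.

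Per the file headers, the authors deposited for each contig its length, the count of all reads, the count of uniquely assigned reads, and an RPKM. The contigs are those of a transcriptome that the series' design text says was assembled de novo. The aligner, the counting tool and the treatment of reads that match several contigs are not given in the sources used here. The deposited counts are whole numbers and were not normalized. The deposited RPKM equal the total reads divided by contig length and by the column's total, to within 0.0078 RPKM in any cell, and were not used further. Each file lists the same 149594 contigs (median length 348 nt, range 78 to 12003 nt). The files pair no gene names with the contig identifiers and no genome was used here, so no contig is given a gene name, a position or an annotation. For this reason 20 planned lists of genes by description could not be tested. A de novo assembly can split a gene into several contigs, so numbers of contigs are not numbers of genes.

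Library totals ran from 22038256 to 31266924 reads, of which 96.45% to 97.09% were uniquely assigned. Total reads per contig were analysed with edgeR 4.0.16 in R 4.3.3. Contigs were kept by filterByExpr, which left 62408 contigs holding 99.191% to 99.571% of each library's reads. Scaling used TMM factors, which ranged from 0.9075 to 1.092. One quasi-likelihood model with a mean per group was fitted to all 12 libraries, so that the 4 groups share one estimate of the spread. Of the 5 planned comparisons, 4 set one group against another and 1 tested the difference between the Reg+ and Reg- amputation responses (the interaction). A contig was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. In the comparisons of 2 groups a fold change is positive when the group named first is higher. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Where a group has few reads, this value can be smaller than counting error alone and is not a reliable measure of precision. Where a group had no read of a contig, a fold is given as a lower bound against 3 reads over the whole group. Where it had 5 or fewer, the ratio of summed reads is given with a 95% exact (Clopper-Pearson) interval. These bounds and intervals cover counting error only. For library similarity, Spearman correlations and principal components were computed on log2 CPM with a prior count of 2. Fitted fold changes used the default prior count of the edgeR fit instead.

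The comparisons, the rule for the contigs named in the text and a first set of other settings (given last) were fixed before the data were examined. Per comparison the named contigs are the 2 with the largest positive and the 2 with the largest negative log2 fold change among called contigs with a mean of at least 1 CPM over the 12 libraries. For comparisons of 2 groups the libraries of the groups must also not overlap in CPM. No contig was named for the comparison of the 2 amputated groups.

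The model was tested on simulated counts drawn with the real means, depths and dispersions, with 200 of the 62408 contigs changed. The changed contigs were all drawn from those with a mean of at least 1 CPM, so the shares do not cover contigs below that level. Apart from these changes all groups had the same mean per contig, and no library was made to stand apart from its group. For Reg+ amputated against uncut it called 16% of contigs changed 2-fold, 76% of those changed 4-fold and 92% of those changed 8-fold, with 9 false calls among 148. For Reg- amputated against uncut the shares were 10%, 74% and 88%. For the interaction they were 0%, 50% and 84%. For an amputation effect averaged over both regions they were 40%, 92% and 100%.

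Replicates of one group were compared before use. Over contigs with at least 20 reads, chi-square per degree of freedom was 9.706 in the closest pair and 74.46 in the most distant pair (Reg- amputated replicates 1 and 3), so no library was a repeat of another of its own group within sampling noise. Pairs across groups were not compared in this way. The labels do not say that a replicate number marks a shared origin, and the main model has no replicate block. The first set of other settings was RLE size factors, DESeq2 1.42.0, no low-count filter, a mean of at least 1 CPM, libraries of the 2 groups only, a replicate block, and leaving out each library. Settings added after seeing the data were uniquely assigned reads, thinning to the smallest library, 1 surrogate variable (sva 3.50.0), robust moderation, and leaving out the 20 most abundant contigs. The labels and files give no sequencing batch or date.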

Results

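Gene expression next to a wound was measured by RNA-seq in *Procotyla fluviatilis*, to ask which transcripts amputation had changed after 24 hours in a body region that can regenerate (Reg+) and in one that cannot (Reg-). Each of 4 groups (Reg+ amputated, Reg+ uncut, Reg- amputated and Reg- uncut) had 3 libraries, each from a pool of 3 worms. Uncut tissue of the same region was the control for each amputation. The libraries held 22038256 (Reg+ uncut replicate 3) to 31266924 (Reg+ amputated replicate 1) reads. The most abundant contig, 1572 nt long, took 3.239% to 6.135% of a library. Of 149594 contigs, 62408 had enough reads to be tested. Contigs of the de novo transcriptome are given by the identifier in the files, which pair them with no gene name, and groups are named as the labels name them.

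The libraries did not group by region or by treatment. Libraries labelled Reg+ amputated were closest to those labelled Reg- uncut, with a mean Spearman correlation of 0.9565 over 9 pairs, and this was near the 0.9655 found among the Reg+ amputated libraries themselves. Their correlation with Reg+ uncut, the control of the same region, was 0.8919. Libraries labelled Reg+ uncut and Reg- amputated correlated at 0.9402, against 0.9074 for Reg+ uncut with Reg- uncut and 0.9072 for Reg- amputated with Reg- uncut. Among themselves the Reg+ uncut libraries correlated at 0.955 and the Reg- amputated libraries at 0.9117 (lowest pair 0.861), so the latter were on average less like each other than like Reg+ uncut. For 12 of 12 libraries the most similar other group was the one that differed in both region and treatment, although for Reg- amputated replicate 3 the margin was only 0.9167 against 0.9166. The first principal component held 46.77% of the variance and placed the Reg+ amputated and Reg- uncut libraries between -123.64 and -59.25, and the Reg+ uncut and Reg- amputated libraries between 5.43 and 151.03. Reg- amputated replicate 3 gave the value of 5.43.

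**Figure D1:**
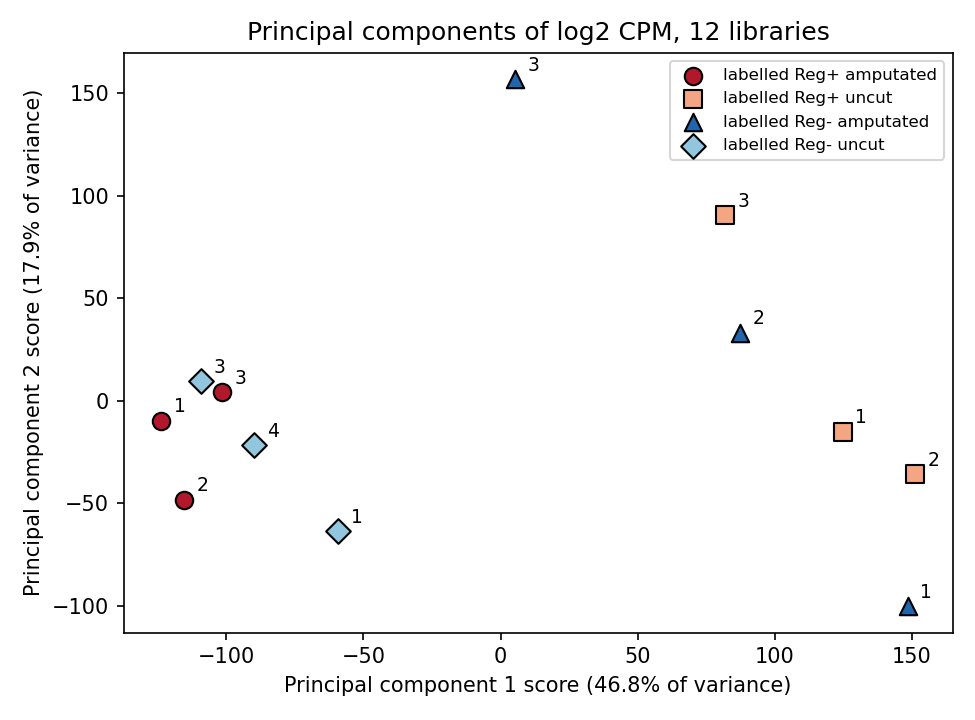
Principal component scores of the 12 libraries from log2 CPM of the 62408 tested contigs, with the share of variance on each axis; symbols give the labelled group and the digits the replicate number. On component 1 the 6 libraries labelled Reg+ amputated or Reg- uncut lie between -123.64 and -59.25 and the other 6 between 5.43 and 151.03.

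In the regenerating region, 4019 contigs differed between amputated and uncut tissue. Of these, 1305 rose and 2714 fell after amputation as labelled (edgeR quasi-likelihood test). Here and in the comparisons below, contrasts and directions hold only as labelled, because an exchange of labels between whole groups stays open. Had region labels been exchanged among the uncut or the amputated groups, each amputation comparison would set tissue of different regions against each other. Reg+ amputated against Reg- uncut and Reg- amputated against Reg+ uncut would then measure amputation. These gave 0 calls each by edgeR, and 542 and 20 by DESeq2. The median log2 fold change was 1.55 among contigs that rose and -1.41 among those that fell, and 1412 contigs changed at least 4-fold. The contigs that rose took 4.71% ± 0.55 (SD, n = 3) of reads in amputated and 1.96% ± 0.16 in uncut tissue. Those that fell took 2.59% ± 0.37 and 7.24% ± 1.04. The same sets of contigs were at 4.84% ± 0.27 and 3.70% ± 0.21 in the Reg- uncut libraries, which are not part of this comparison.

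Among the named contigs of the regenerating region, contig130914 (230 nt) had 112 to 499 reads in each amputated library and none in 3 uncut libraries. It was at least 255-fold higher after amputation (adjusted p 0.00125 by edgeR). The shorter contig131703 (204 nt) stood at 36.0 ± 2.19 CPM in amputated and 0.043 ± 0.075 CPM in uncut tissue (n = 3 each), a log2 fold change of 9.74 with a standard error of 0.56 and an adjusted p of 6.13e-06 by edgeR. All 3 uncut reads were in uncut replicate 3, without which the log2 fold change was 12.99. Its ratio of summed reads was 963, with an interval from 329 to 4670. This interval, from counting error alone, is wider than that standard error implies, so the standard error is too small. In the other direction, contig115537 (450 nt) had no read in any amputated library and 236 to 1017 in the uncut libraries, and was at least 588-fold lower (adjusted p 0.00834 by edgeR). Likewise, contig117790 (285 nt) had no read after amputation against 184 to 604 reads, and was at least 436-fold lower (adjusted p 0.00264). The number of calls in this comparison fell to 1747 without amputated replicate 1, to 1753 without amputated replicate 2, to 1944 without uncut replicate 1 and to 2647 without uncut replicate 3. The number was 6184 with DESeq2, 7217 with 1 surrogate variable, and 6367 when only these 2 groups were fitted, where 53.6% instead of 32.5% of the calls were higher after amputation as labelled. An exchange of treatment labels in this region, which stays open, would turn these directions. With an exchange of region labels, which stays open too, these calls would not be an amputation response alone.

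In the region that does not regenerate, 1632 contigs differed between amputated and uncut tissue, of which 1011 rose and 621 fell after amputation. As labelled, the median log2 fold change was 4.24 among contigs that rose (3.94 with contigs that had no uncut read set at their lower bound) and -2.06 among those that fell. The contigs that rose took 2.31% ± 0.60 (SD, n = 3) of reads in amputated and 0.48% ± 0.01 in uncut tissue, and 3.04% ± 0.91 in the Reg+ uncut libraries outside this comparison. Those that fell took 1.11% ± 0.07 and 3.20% ± 0.20, and 2.64% ± 0.24 in the Reg+ amputated libraries.

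By fitted fold change, which depends on the prior count of the fit where a group has no read, the first contigs raised in this region were contig3830 (247 nt) and contig126409 (227 nt). The former had 83 to 639 reads in the amputated libraries, the latter 163 to 336, and neither had a read in any uncut library, so that they were at least 390-fold and 230-fold higher (adjusted p 0.00254 and 0.000193 by edgeR). The first lowered by the same order were contig119958 (368 nt) and contig109086 (442 nt). No read of contig119958 was found after amputation against 17 to 151 in uncut tissue, at least 85.9-fold lower, a smaller bound than the ratio of contig109086. Its adjusted p was 0.0356 by edgeR, and between 0.0692 and 0.0962 without amputated replicate 1, 2 or 3 or uncut replicate 1 or 3. Reads of contig109086 numbered 2 over 3 amputated libraries, both in replicate 1, and 256 to 791 in each uncut library, a ratio of 732 with an interval from 202 to 6050 and an adjusted p of 8.63e-05. The number of calls was 2727 with 1 surrogate variable, with 45.9% instead of 61.9% higher after amputation. Fitting only these 2 groups gave 1045 calls and adjusted p of 0.0613 for contig3830 and 0.134 for contig119958.

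The 2 amputation responses share no library, and contigs called in both nearly all ran in opposite directions. Of the 1632 contigs called in Reg- tissue, 79.5% were also called in Reg+ tissue, and 1296 of these 1298 contigs changed in opposite directions. There were 860 that fell in Reg+ and rose in Reg-, where independent lists would share 44.0, and 436 that rose in Reg+ and fell in Reg-, where 13.0 would be shared. No contig rose in both regions, against 21.1 for independent lists. Only 2 fell in both, against 27.0 for such lists. Across contigs, which are not independent replicates, the log2 fold changes of the responses correlated with a Pearson r of -0.674 and a Spearman rho of -0.405, and 64.7% of the 62408 tested contigs had opposite signs in the 2 responses.

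The 860 contigs that fell in Reg+ and rose in Reg- were near the detection limit in 2 groups and expressed in the others. Their median level was 0.159 ± 0.022 CPM in Reg+ amputated and 0.152 ± 0.042 CPM in Reg- uncut tissue (SD, n = 3 each). It was 8.35 ± 2.74 CPM in Reg+ uncut and 5.99 ± 2.08 CPM in Reg- amputated tissue. The 436 contigs with the reverse pattern stood at 9.99 ± 1.79 CPM in Reg+ amputated and 11.5 ± 1.15 CPM in Reg- uncut tissue, against 1.18 ± 0.24 CPM in Reg+ uncut and 1.25 ± 0.29 CPM in Reg- amputated tissue. In both sets the higher group of each region was set by the selection, made on these same libraries. The levels are therefore no separate evidence for the pattern.

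**Figure D2:**
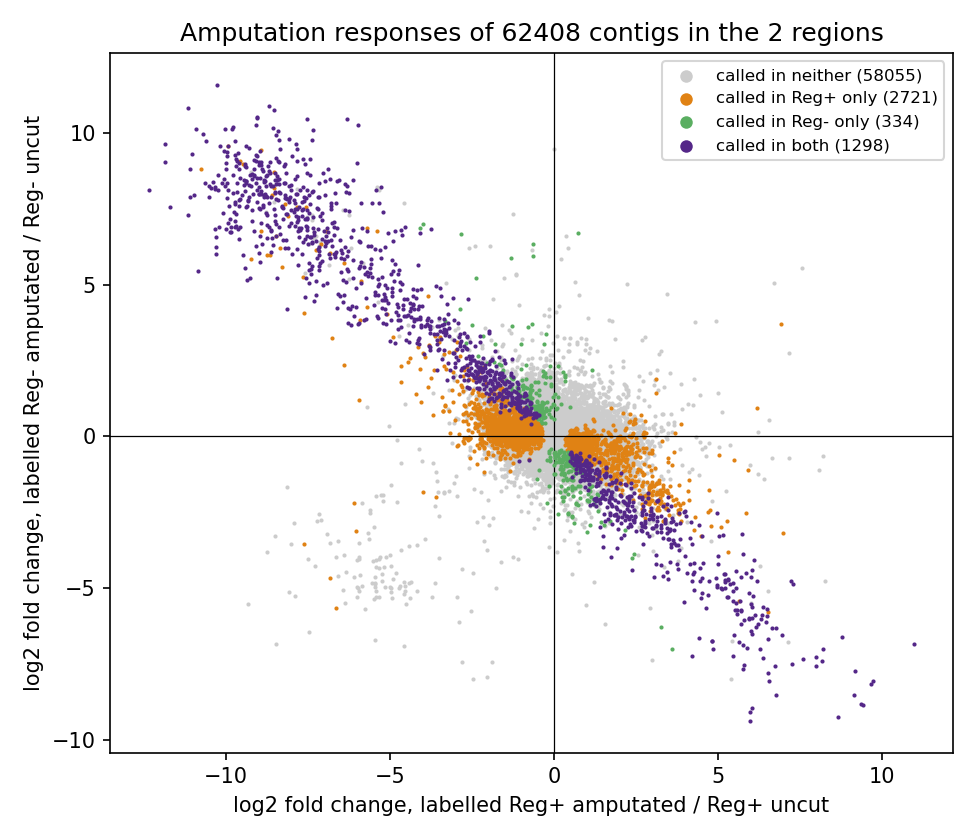
Log2 fold change of each of 62408 contigs after amputation in the region labelled Reg+ (x axis) and in the region labelled Reg- (y axis); each point is a contig and the colour says in which comparison it was called. Nearly all contigs called in both (1296 of 1298) lie in the upper left or the lower right of the plot.

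The difference between the 2 responses was tested as an interaction. It was called for 4634 contigs, of which 1878 had the higher amputation response in Reg+ and 2756 the higher response in Reg-. The contigs with the largest fitted differences are given next. Ranking by this contrast favours contigs high in Reg+ amputated and Reg- uncut tissue, or low in both. Their pattern is therefore no separate evidence for the grouping of the libraries. Expression of contig10249 (329 nt) was 46.6 ± 30.2 CPM in Reg+ amputated and 38.7 ± 17.9 CPM in Reg- uncut tissue, with 0.069 ± 0.091 and 0.083 ± 0.073 CPM in Reg+ uncut and Reg- amputated tissue (SD, n = 3 each). That of contig10075 (470 nt) was 44.2 ± 7.69 and 47.6 ± 6.42 CPM against 0.064 ± 0.026 and 0.106 ± 0.1 CPM, an interaction of 18.18 on the log2 scale with a standard error of 0.70 and an adjusted p of 1.25e-07 by edgeR. Contig10075 had only 5 reads over the Reg+ uncut and 9 over the Reg- amputated libraries, so that standard error is too small. Its interaction was 19.09 without Reg- amputated replicate 1 and 17.46 without Reg- amputated replicate 3. In the opposite direction, contig66832 (281 nt) had no read in any Reg+ amputated or Reg- uncut library and 10.2 ± 3.43 and 8.15 ± 5.27 CPM in Reg+ uncut and Reg- amputated tissue. For contig3830 the values were 0.011 ± 0.019 CPM and no read, against 20.6 ± 11.3 and 13.7 ± 9.45 CPM. Without Reg- amputated replicate 3 the interaction was called for 12429 contigs, of which 56.7% instead of 40.5% had the higher response in Reg+. Counts of 7740 with 1 surrogate variable and of 2905, 2917 and 3059 were found without Reg+ amputated replicate 1, Reg+ amputated replicate 2 and Reg+ uncut replicate 1.

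**Figure D3:**
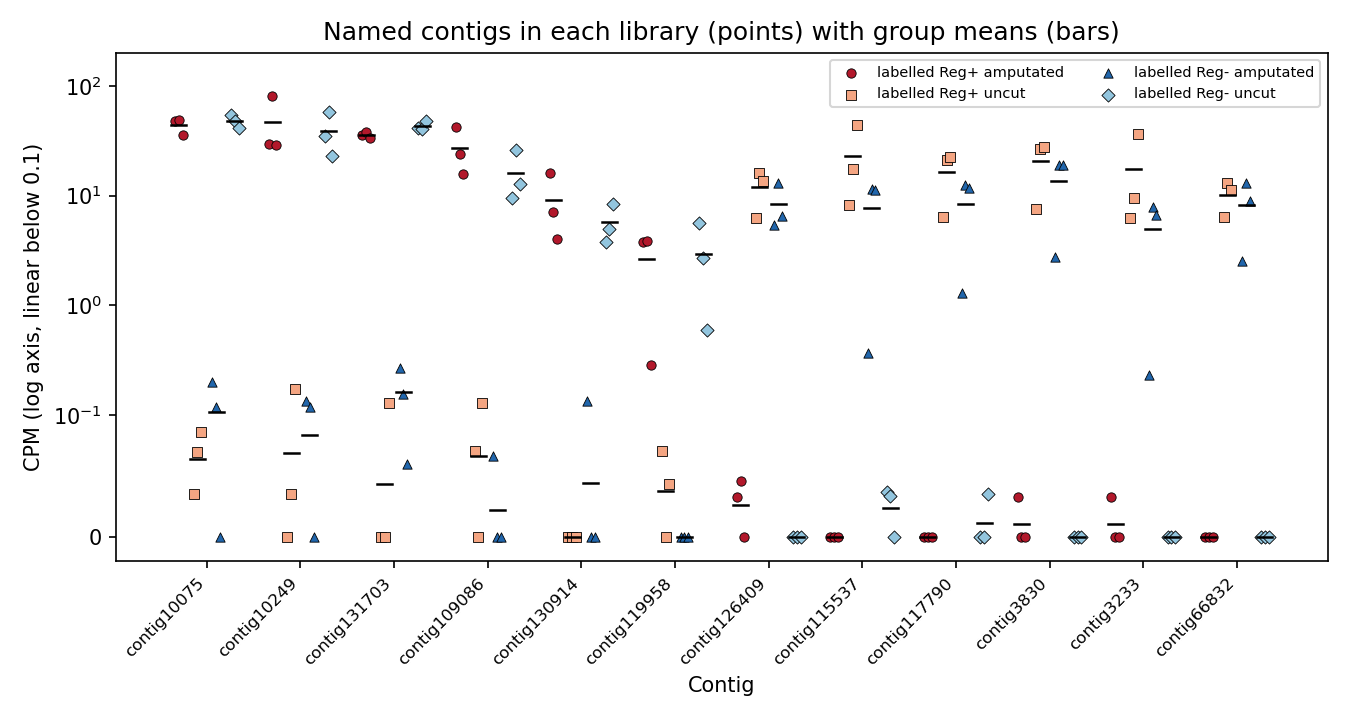
CPM of the named contigs in each of 12 libraries, on a log axis that is linear below 0.1; points are libraries, bars are group means and the symbols give the labelled group. The contigs are expressed either in the libraries labelled Reg+ amputated and Reg- uncut or in those labelled Reg+ uncut and Reg- amputated.

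Uncut tissue of the 2 regions was compared to measure regional expression without a wound. It differed at 2049 contigs, with 1256 higher in Reg+ and 793 higher in Reg-. Contigs higher in Reg+ had a median log2 fold change of 3.30 and took 4.07% ± 0.97 of reads in Reg+ uncut and 0.97% ± 0.04 in Reg- uncut tissue (SD, n = 3). Contigs higher in Reg- took 4.03% ± 0.25 of reads there and 1.35% ± 0.07 in Reg+ uncut tissue. In amputated tissue the order was the other way round, since the first set took 1.08% ± 0.05 of reads in Reg+ and 3.05% ± 0.60 in Reg- amputated libraries, and the second 3.43% ± 0.39 and 1.5% ± 0.17. The largest fitted fold changes in favour of Reg+ were in contig3830 (247 nt) and contig3233 (551 nt), which had no read in any Reg- uncut library and were at least 579-fold and 464-fold higher in Reg+ (adjusted p 0.00154 and 0.0122 by edgeR). The largest fitted ones in favour of Reg- were in contig130914, with no read in Reg+ uncut tissue and at least 154-fold higher in Reg- (adjusted p 0.00197), and contig131703, with 3 reads over 3 Reg+ libraries, all in replicate 3, and 1123 to 1394 in each Reg- library, a ratio of 1170 with an interval from 401 to 5680. This order is not one of measured ratios: contig10075 stood at 47.6 ± 6.42 CPM in Reg- uncut and 0.064 ± 0.026 CPM in Reg+ uncut tissue. With 1 surrogate variable 1359 contigs were higher in Reg+ and 1531 in Reg-, so that the larger share changed sides.

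Amputated tissue of the 2 regions differed at 2085 contigs, of which 602 were higher in Reg+ and 1483 higher in Reg-. Contigs higher in Reg+ took 3.21% ± 0.42 of reads in Reg+ amputated and 1.30% ± 0.02 in Reg- amputated tissue (SD, n = 3). Contigs higher in Reg- took 1.29% ± 0.21 and 4.08% ± 0.96. In uncut tissue the first set stood at 1.33% ± 0.03 of reads in Reg+ and 3.41% ± 0.20 in Reg-, and the second at 4.85% ± 1.02 and 2.01% ± 0.15. The count depended on Reg- amputated replicate 3, without which 5525 contigs were called and 52.0% instead of 28.9% of them were higher in Reg+. It was 1088, 1060 and 1279 without Reg+ amputated replicate 1, Reg+ amputated replicate 2 and Reg- amputated replicate 2, 3349 with DESeq2, 5252 with 1 surrogate variable, and 869 when only the 2 groups were fitted.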

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

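The tests of the labels in this part were chosen after the grouping of the libraries had been seen, and the counts over other splits of the libraries were planned before. The groups have 3 libraries each, too few to look for a single outlying sample by its gap to the others. What called for a closer look is that the difference between amputated and uncut libraries, as labelled, was not the same in the 2 regions: 4634 contigs had a called interaction, and 1296 contigs were called in both regions in opposite directions. All 12 named contigs had a called interaction. For contig10249, contig10075, contig66832 and contig3830 this was set by the rule that named them. The others were named for the largest fold changes in comparisons that form part of the interaction. Their calls are therefore no separate evidence for opposite responses either. The log2 interaction was 17.85 for contig130914, 17.81 for contig131703, 15.36 for contig119958, 17.90 for contig109086, 18.29 for contig10249 and 18.18 for contig10075. It was -20.46 for contig115537, -20.90 for contig117790, -21.84 for contig3830, -19.54 for contig126409, -22.0 for contig66832 and -20.13 for contig3233. These values rest on groups with few or no reads, so their size depends on the prior count of the edgeR fit.

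Among the 3 groups other than its own, every library resembled most the one that differs from it in both labels, for Reg- amputated replicate 3 only by 0.9167 against 0.9166. Contigs present in 6 libraries (at least 50 reads in each) and nearly absent from the other 6 (at most 5 reads in each) numbered 166 for Reg+ amputated with Reg- uncut against the rest, of which 15 were present in these groups and 151 in Reg+ uncut and Reg- amputated. They numbered 0 for the split by region and 0 for the split by treatment. A wrong label on 1 library, or a trade of 2, is argued against, since it would move at most 2 libraries and 12 of 12 were closest to that group. An exchange of region labels between the 2 uncut or the 2 amputated groups, or an exchange of treatment labels between the 2 groups of one region, may each have produced the grouping. The first would make Reg+ amputated minus Reg- uncut and Reg- amputated minus Reg+ uncut the 2 amputation responses, the second regional differences of opposite sign, but their correlation across contigs of r = 0.211 had an exact two-sided permutation p of 0.27 (108 of 400 relabellings), which favoured neither. The relabellings took libraries as exchangeable within each pair of groups and did not keep same-numbered libraries together. A response to amputation that truly turns the profile of one region into that of the other remains open too, because in this 2 by 2 design it and an exchange of whole groups cannot be told apart. The labels give no collection, day or sequencing batch, so a factor of that kind shared by these pairs of groups cannot be told apart either.

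For the interaction, 100 splits of the 12 libraries into 4 groups of 3 were drawn at random, with the labelled one included. Of these, 1, the labelled one, gave as many calls, and the highest other gave 4449. That other split parted the libraries almost as the labels do, and so points to the same structure. It had Reg- amputated replicate 3 and Reg- uncut replicate 4 on each other's side. A random grouping of exchangeable libraries is thus argued against as the source of the count. Chance is not excluded, because the labels do not establish that the pools are exchangeable. The contrast sets Reg+ amputated and Reg- uncut against the other groups, so the test asks only whether the grouping already seen is present. The comparisons of 3 with 3 libraries allow only 10 splits, too few for a share under 0.05. In each, 1 split, the labelled one, gave the real count (4019, 1632, 2049 or 2085) and the highest other gave 0.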

How the results depend on the processing

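The tests with uniquely assigned reads, thinning, a surrogate variable, robust moderation and without abundant contigs were chosen after the result was seen, and the others were planned. The direction of the 16 named values was the same in all 292 combinations of a named value with another setting, which share their fits. This was largely set by the naming rule, which took the largest fold changes from these same libraries. It is no separate evidence for the directions. The size of those that rest on few reads moved. Without Reg+ uncut replicate 3, contig131703 went from 9.74 to 12.99 in Reg+ and from -10.02 to -13.27 between the uncut groups. Without that library the interaction of contig10249 went from 18.29 to 19.87. The value of contig109086 in Reg- went from -9.23 to -11.81 without Reg- amputated replicate 1. The interaction of contig3830 went from -21.84 to -23.73 without Reg+ amputated replicate 1. In 8 of the 292 combinations the adjusted p went over the threshold (7 for contig119958 and 1 for contig3830 in the Reg- comparison). RLE scaling, uniquely assigned reads, thinning, robust moderation, both low-count filters and the removal of the 20 most abundant contigs left each of the 5 counts within 1.5 times its value. DESeq2 called 6184 contigs for amputation in Reg+ and 3349 between the amputated groups. Fitting only the libraries of the 2 groups gave 6367 for Reg+, 1045 for Reg- and 869 between the amputated groups. With 1 surrogate variable the counts were 7217 for Reg+ (48.8% of calls higher, against 32.5%), 2727 for Reg- (45.9%, against 61.9%), 7740 for the interaction (54.6%, against 40.5%) and 5252 between the amputated groups (51.1%, against 28.9%). Between the uncut groups this left the count within 1.5 times but took the share of higher calls from 61.3% to 47.0%. Leaving out 1 library gave 1747 to 3820 calls for Reg+, 1133 to 1857 for Reg-, 2905 to 12429 for the interaction, 1380 to 1750 between the uncut groups and 1060 to 5525 between the amputated groups; the upper values of the interaction and of the amputated groups are those without Reg- amputated replicate 3. The cause was not tested in any of these. The count of contigs changed in opposite directions ranged from 925 to 1786 over all alternatives. With the replicate block the counts were 4889, 1327, 4787, 1634 and 2092 in the order of the report, with no named call lost. The labels do not tie the numbers to a shared origin. Same-numbered libraries' deviations from their group means correlated at -0.03, 0.26 and 0.08 for Reg+ amputated with Reg+ uncut, -0.10, 0.18 and 0.10 for the amputated groups, 0.34, 0.15 and 0.58 for Reg+ uncut with Reg- amputated, 0.29 and 0.35 for Reg- amputated with Reg- uncut, -0.05 and 0.34 for the uncut groups, and -0.09 and 0.02 for Reg+ amputated with Reg- uncut. These were not all over 0.1, so the numbers were not taken as pairs. All those of Reg+ uncut with Reg- amputated and of Reg- amputated with Reg- uncut were over 0.1, and a shared origin of some same-numbered libraries stays open. Some pairs of different number were also high, as at 0.37 for Reg+ uncut replicate 2 with Reg- uncut replicate 1. Of 12 libraries, 7 correlated best with a library of their own number, and Reg- uncut replicate 4 had no library of its number to match. The number to be found without a shared origin was not computed. Settings meant for normalized values did not apply to counts, and the gene list tests were not run for want of names. Depth limits statements on contigs absent from a group, whose folds are lower bounds.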

Other observations

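The tests in this part on sequencing depth, on another organism and on the 85 contigs lower in both amputated groups were chosen after the result was seen, and the test of admixture was set before its value was known. Comparing groups across the labels, added after seeing the data, gave fewer calls than the comparisons of the report. Between Reg+ amputated and Reg- uncut tissue, 0 contigs were called by edgeR (5792 with an unadjusted p under 0.05, smallest adjusted p 0.0533), 542 by DESeq2, of which 101 were higher in Reg+ amputated tissue, and 141 by edgeR with 1 surrogate variable. Other edgeR settings called 29 without Reg+ amputated replicate 3, 11 with only the 2 groups, 10 with no low-count filter, 4 with the replicate block, and 1 each with a mean of at least 1 CPM and after thinning. Between Reg- amputated and Reg+ uncut tissue, 0 were called by edgeR (2374 with an unadjusted p under 0.05), 2 with 1 surrogate variable and 20 by DESeq2. For the amputation effect averaged over both regions, 0 contigs were called by edgeR, although 5324 (8.53%, where 5% would be expected without any change) had an unadjusted p under 0.05, and DESeq2 called 195, of which 29 rose and 166 fell. Here edgeR called 2 with 1 surrogate variable and 1 with no low-count filter. The region effect averaged over both treatments gave 0 contigs by edgeR, 2965 (4.75%) with an unadjusted p under 0.05, and 36 by DESeq2, with 4 by edgeR under the replicate block, 3 with 1 surrogate variable and 1 with no low-count filter.

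A set of 85 contigs had log2 fold changes below -3 after amputation in both regions, while 6 had values above 3 in both. Of the 85, 4 were called in Reg+ and 0 in Reg-. Their reads were concentrated in single pools: the summed reads were 16895 in Reg+ uncut replicate 2, 10300 in Reg- uncut replicate 1, 2889 and 1811 in the other Reg+ uncut libraries, 140 and 411 in the other Reg- uncut libraries, and at most 349 in any amputated library. Picking contigs lower after amputation in both regions favours uncut libraries of both regions in the highest ranks, but not particular ones. In 85.9% of the contigs (73 of 85) the same 2 libraries ranked first and second, and the log2 ratio between them had a median of 0.82 (quartiles 0.54 and 1.05). This is consistent with 1 source present in different amounts in the pools, such as another organism carried by field-collected worms or cells of the worm itself, and without the contigs' sequences these cannot be separated.

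The library Reg- amputated replicate 3 stood apart. It had no read for 20944 contigs, against 27897 to 40491 in the other 11 libraries, and 210 contigs had at least 10 reads in it and at most 2 in all others together, against 0 to 4. Depth is argued against: after thinning every library to the smallest total there were 141 such contigs in it against at most 2 elsewhere. Tissue or RNA of the Reg+ amputated and Reg- uncut kind mixed in is argued against as well, since 17 contigs of that kind, with at most 5 reads in each of the other 5 libraries of Reg+ uncut and Reg- amputated, stood at a median of 0% of their level there, and the same measure in each of those 5 was 0.249% to 0.906%. No biological explanation was tested. Material of another organism in this pool may account for the 210 contigs, which hold 3617 reads, but their sequences were not searched. Its deviations from the group mean correlated at 0.58 with those of Reg+ uncut replicate 3 and at 0.35 with those of Reg- uncut replicate 3, which carry the same number, and those 2 correlated with each other at 0.34. With Reg+ amputated replicate 3 it correlated at 0.097. Some libraries of different number correlated as highly as 0.35, though not as 0.58. Reg+ uncut replicate 2 correlated at 0.37 with Reg- uncut replicate 1 and at 0.35 with Reg- amputated replicate 1. Something shared by libraries of this number was not tested as an explanation and stays open.

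Among the 20 most abundant contigs, the widest spread within a group was in a contig of 911 nt, with 3496 to 199301 reads in the Reg+ amputated libraries, a 63.7-fold range in CPM.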
